A study of Mus musculus with 6 samples.

How the data were processed

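Total RNA with an RNA integrity number of at least 7 was made into stranded poly(A) libraries and read as paired ends of 125 or 150 bases, per the labels' protocols. Alignment with HISAT2 2.2.1.0 and the builds GRCm38.p6 and mm10 are named per the submitters' processing notes. The authors deposited raw read counts per gene, as whole numbers with different totals per library, and the counting tool, its strand setting and any filter are not given in the sources used here. Reads shared between near-identical genes could therefore have been split or dropped, which leaves families such as Ifit, Gbp, H2 and Hspa1 uncertain. Gapdh, a glycolysis gene with many pseudogene copies, stood at 21.1 CPM with β-elemene and 19.3 with PBS, where Ldha stood at 900 and 896, as if reads that fit several places had been dropped. Genes with such copies in the glycolysis and ribosomal protein lists are uncertain for the same reason, and so are the values of those lists. Where strand was not used in counting, antisense partners cannot be told apart.

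The table held 21878 genes, of which 6562 had no count in any library. A spreadsheet had turned 27 gene symbols into date numbers, and these were restored from their gene identifiers with the NCBI gene table of the same build, GRCm38.p6, which gave the coordinates too. Of the restored genes, 19 were tested. Sepp1 and Dfna5 were matched to newer symbols by gene identifier. Cxcl11, Ighm, Mx1, Mx2, Tpsab1 and the mitochondrially encoded genes were not analysed here. Groups and replicate numbers came from the sample titles. Each library counted as 1 replicate. No pair of replicates agreed within sampling noise, with chi-square per degree of freedom between 3.70 and 13.2. That comparison is with counting noise alone, so it cannot tell separate cultures from separate preparations of the same RNA.

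Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 11459 genes, and scaled with TMM, whose factors were 0.794 to 0.812 with β-elemene and 1.24 to 1.26 with PBS. The 10 most abundant genes took 9.09% to 9.50% of the counts with β-elemene and 10.3% to 11.3% with PBS. Differences were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, 4 residual degrees of freedom), with group as the only term and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The SE was derived from the log2 fold change and the F statistic. The common biological coefficient of variation was 0.0709. For genes with at most 3 counts over a group, the ratio of summed counts, each divided by the summed effective library size of its group (total counts times TMM factor), is given with an exact 95% binomial interval scaled in the same way. With 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group, scaled likewise. The interval and the floor cover counting error only, since the reads carry no molecular identifiers.

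Before the data were examined, 44 gene lists (functional programmes, cell type markers and library quality) were fixed, and 39 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The named genes were fixed by rule at the same time. They were the 12 largest rises and 12 largest falls among passing genes with an ordinary symbol, a mean of at least 5 CPM and groups that do not overlap, a panel of polarisation, checkpoint and VEGF genes, up to 4 passing members per list with a mean of at least 1 CPM by size of change with up to 2 of the opposite sign, and the most abundant member of each marker list. Some genes that this rule selects are not reported here.

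The alternatives were size factors by median of ratios, the upper quartile and library size alone, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, and for lists an estimated correlation, ranks and fry. The pipeline was tested on simulated counts for this comparison, with 200 of 11459 genes changed. It called 81.8% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 0 calls of the wrong sign. Unchanged genes made up 9.25% of the calls on average over 10 draws (5.62% to 12.6%), above the 5% that the threshold aims at. In the data 8791 of 11459 genes changed, far more than were simulated. These shares therefore cannot be carried over to the calls made there. With each gene's dispersion placed on the fitted trend, the mean share of unchanged genes among the calls was 5.37%. The excess in the simulation thus went with genes whose spread lies far from the trend. With each gene's own dispersion, as in the draws that gave 9.25%, 4.79% of unchanged genes had an unadjusted p below 0.05. A simulated shift of the NF-kB list was called, as was 1 of 38 other lists, the chemokine list, which shares members with it. The simulated genes were drawn independently of one another. The simulation therefore cannot show how often lists of correlated genes are called without a shift. Figures were drawn with matplotlib 3.10.9.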

Results

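RNA sequencing was done on mouse bone marrow-derived macrophages, which were grown from C57BL/6 marrow in medium with macrophage colony-stimulating factor at 50 ng/mL. The macrophages shared medium with LLC cells, a mouse lung carcinoma line, for 48 h across a transwell membrane with 0.4 µm pores. The medium was then changed, and the cells received β-elemene, a plant sesquiterpene, at 100 µg/mL or an equal volume of phosphate-buffered saline (PBS) for 24 h. There were 3 libraries per group, assigned by their sample titles. The submitters' library names carry M1 for the β-elemene group and M2 for the PBS group, and the labels do not say what those letters stand for, so each value below holds for the groups as titled. Total gene counts were 20344299, 18916844 and 20550078 in β-elemene replicates 1, 2 and 3, and 20524959, 20729887 and 20678051 in PBS replicates 1, 2 and 3. A gene with 0 counts in a library could have held up to 3 counts, or between 0.116 and 0.195 CPM (counts after TMM scaling, relative to library size), and this limit covers counting error only. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure the spread between these 6 libraries, which may be technical. Values below are mean CPM ± SD with n = 3 per group, and log2 fold changes are β-elemene over PBS with their standard error (SE).

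The comparison asked which transcripts differ between drug and vehicle in macrophages conditioned by tumour cells. Of the tested members of gene lists, 28 of 29 classical activation genes and 32 of 32 interferon-stimulated genes were higher in the β-elemene libraries, and 15 of 24 alternative activation genes and 25 of 26 mitosis genes were lower. These list calls were made with a preset correlation, and none held with an estimated correlation (camera adjusted p of 0.20, 0.20, 0.20 and 0.79). The test with an estimated correlation has far fewer degrees of freedom, so a lost call is not by itself a sign of correlated genes. Nos2, the inducible nitric oxide synthase, stood at 3263 ± 532 CPM against 4.94 ± 2.31, and Rsad2, an antiviral enzyme, at 12873 ± 1471 against 19.8 ± 0.767. Mrc1, the mannose receptor, stood at 94.0 ± 7.88 CPM against 2343 ± 103. In all, 8791 of 11459 genes tested changed (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 4189 of them higher and 4602 lower with β-elemene. Of these, 4046 changed at least 2-fold, 1951 higher and 2095 lower, and 292 rose and 170 fell at least 16-fold. The groups did not overlap for 79.9% of the genes tested, where chance gives 10% for 3 against 3. The balance of directions rests on the scaling. With library size alone in place of TMM, 2166 genes were higher and 8003 lower, the upper quartile gave 2947 higher and 6528 lower, and library size alone moved the median log2 fold change of all genes by -0.64.

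**Figure D1:**
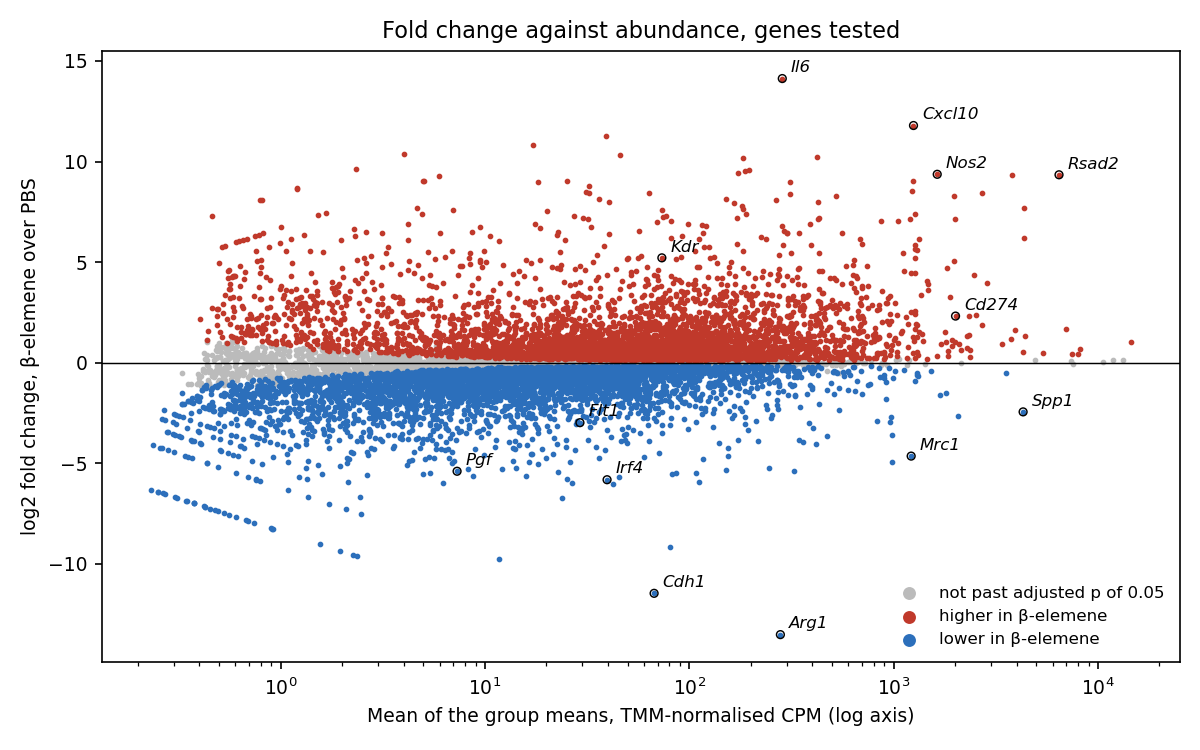
Log2 fold change, β-elemene over PBS, against the mean of the group means in TMM-normalised CPM on a log axis, with 1 point per gene tested. Red points are the 4189 genes higher and blue points the 4602 genes lower past an adjusted p of 0.05, and grey points did not pass. Il6 lies highest at 14.13 and Arg1 lowest at -13.51, while Flt1 lies at -2.98.

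The 12 largest rises were taken among genes with a mean of at least 5 CPM whose groups did not overlap. Cxcl10, a chemokine for T cells, rose from 0.700 ± 0.281 to 2501 ± 475 CPM (log2 fold change 11.79, SE 0.27, edgeR adjusted p = 2.71e-09). Il6 (chromosome 5, 30013114 to 30019975, GRCm38.p6) had 27375 counts over the β-elemene libraries and 2 over the PBS libraries, which after TMM scaling of the libraries is a ratio of 22049 with a 95% counting interval of 6103 to 182079. Il12b, the shared subunit of interleukins 12 and 23, had 3780 and 2 counts, a scaled ratio of 3045 (842 to 25150), and Vnn3, a vanin family gene, had 1649 and 1 (scaled ratio 2656, 476 to 104985). The 1 count of Vnn3 lay in PBS replicate 2, and its fitted log2 fold change of 10.83 was 12.42 without PBS replicate 2, though fitted values at such counts are no bound. Fpr1, a formyl peptide receptor, Lipg, endothelial lipase, Tnfsf15 and Il27 rose by log2 fold changes of 10.35, 10.22, 10.17 and 9.57. Fpr1 had 0, 1 and 4 counts in the PBS libraries. Without PBS replicate 3 the log2 fold changes of Fpr1, Il27 and Ifit3b were 11.81, 10.26 and 10.39. Ifit3b and Ifit1bl1, members of an interferon-induced family whose near-identical copies make single members uncertain, rose by 9.55 and 9.45. The remaining genes of the 12 with the largest rises were Nos2 (9.37, SE 0.36) and Rsad2 (9.34, SE 0.13).

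The 12 largest falls were taken by the same rule. Arg1, arginase 1 (chromosome 10, 24915207 to 24927470), had 2 counts over the β-elemene libraries and 43095 over the PBS libraries, which after TMM scaling is a ratio of 13376 with a 95% counting interval of 3703 to 110453. Cdh1, E-cadherin (chromosome 8, 106603350 to 106670247), had 2 and 10386 counts (scaled ratio 3224, 892 to 26622), and Il31ra had 1 and 1813 (scaled ratio 1125, 202 to 44477). The fitted log2 fold change of Cdh1, -11.46, was -14.52 without β-elemene replicate 2, and that of Il31ra, -9.77, was -11.99 without β-elemene replicate 1. Those libraries held all the β-elemene counts of the gene in question. Pald1 fell by 9.18 on the log2 scale, from 160.4 ± 3.48 to 0.272 ± 0.0461 CPM. Bmf, a pro-apoptotic BCL2 family gene, fell by 6.73, Plekhf1 fell by 6.03, Cnr2, the cannabinoid receptor of immune cells, fell by 6.00, and Etl4 fell by 5.99. Ptgs1, cyclooxygenase 1, fell by 5.93, Irf4, a transcription factor, fell by 5.81, Tbc1d16 fell by 5.77, and Socs2, a cytokine signalling inhibitor, fell by 5.67. The edgeR adjusted p of these 12 genes was at most 3.52e-09, the value for Arg1.

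Series metadata name reprogramming of tumour-associated macrophages towards an M1 state as the study's subject. Of 29 tested members of the classical (M1) activation list, 28 rose and 1 fell (camera adjusted p = 1.31e-27 with a preset correlation; adjusted p = 0.20 with an estimated correlation). Tnf rose from 12.8 ± 2.33 to 1719 ± 79.0 CPM and Il1b from 15.5 ± 6.52 to 5394 ± 727. The costimulatory ligands Cd80 and Cd86 rose by log2 fold changes of 2.77 (SE 0.17) and 3.28 (SE 0.17). Tlr4, the lipopolysaccharide receptor, was the member that fell, from 208 ± 5.83 to 87.4 ± 8.60 CPM. Of 24 tested members of the alternative (M2) activation list, 15 fell, 4 rose and 5 did not pass (camera adjusted p = 4.77e-08 with a preset correlation; adjusted p = 0.20 with an estimated correlation). Chil3 fell by 4.94 on the log2 scale (SE 0.14), Mrc1 (chromosome 2, 14229414 to 14332023) fell by 4.64 (SE 0.08), and Irf4, Socs2 and Arg1 are given above. Ccl22 and Il1rn, the interleukin-1 receptor antagonist, rose by 3.22 and 2.35, and Il10 rose by 1.06 (SE 0.26, edgeR adjusted p = 0.0094), a call lost with library size alone at 0.42 (adjusted p = 0.149; range over alternatives 2.13e-07 to 0.149). Retnla (2 counts with β-elemene and 42 with PBS) and Cd163 (2 and 25) did not pass the filter and were not tested. Their summed counts were lower with β-elemene, by scaled ratios of 13.04 (95% counting interval 3.39 to 111) and 7.76 (1.93 to 67.6), which cover counting error only. For Retnla the groups overlapped, with 0 CPM in PBS replicate 2 and 0.130 CPM in β-elemene replicate 2.

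**Figure D2:**
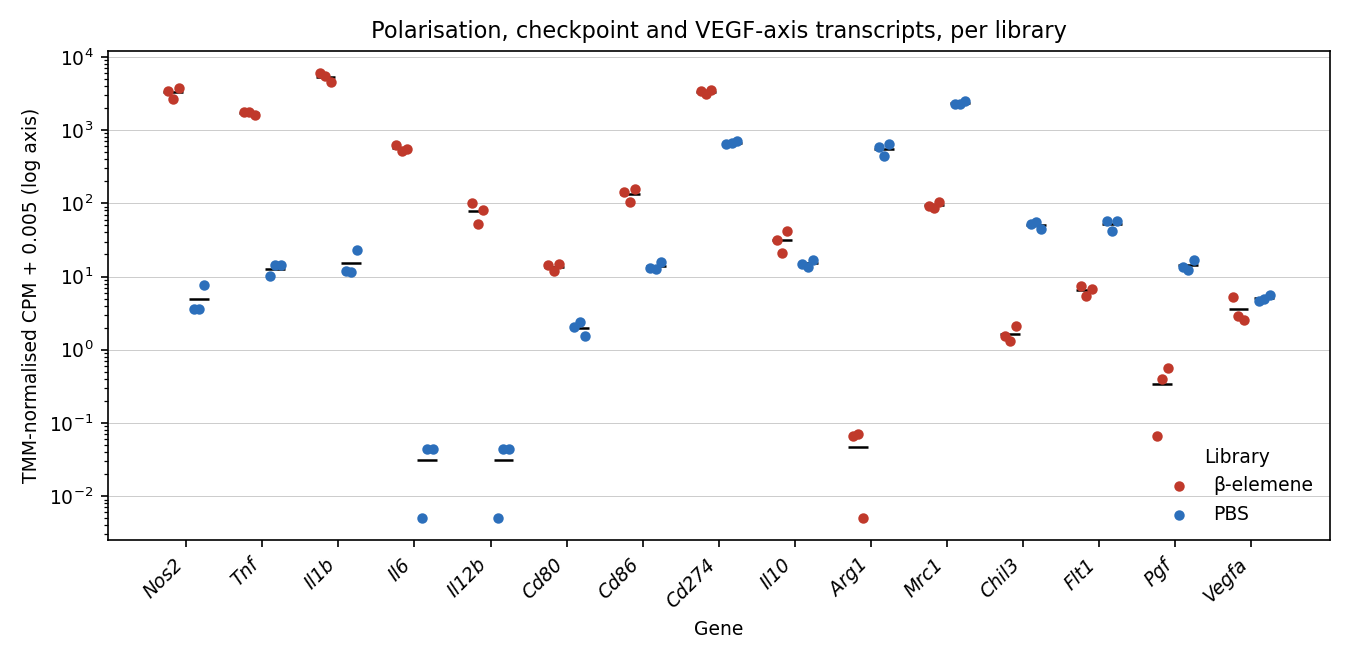
TMM-normalised CPM plus 0.005 on a log axis for 15 genes, with 1 point per library (red, β-elemene; blue, PBS; 3 libraries each) and a bar at each group mean. The 3 β-elemene libraries lie above the 3 PBS libraries for Nos2, Tnf, Il1b, Il6, Il12b, Cd80, Cd86, Cd274 and Il10 and below them for Arg1, Mrc1, Chil3, Flt1 and Pgf, and the groups overlap for Vegfa.

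The series title names FLT1, a receptor for vascular endothelial growth factor (VEGF), with PI3K and AKT signalling. Flt1 (chromosome 5, 147561604 to 147726438) fell from 51.8 ± 8.49 to 6.55 ± 1.02 CPM, a log2 fold change of -2.98 (SE 0.15, edgeR adjusted p = 2.90e-08). Its ligand gene Pgf, placental growth factor, fell by 5.39 on the log2 scale (SE 0.30), and Vegfa stood at 3.60 ± 1.48 against 5.04 ± 0.443 CPM (log2 fold change -0.48, SE 0.23, edgeR adjusted p = 0.075; 4.33e-04 to 0.311 over the alternatives). Kdr and Flt4, which encode the other VEGF receptors, rose by 5.21 and 4.13. In the list of VEGF ligands and receptors, 3 of 9 tested members rose, 4 fell and 2 did not pass (camera adjusted p = 0.768). Of 27 PI3K, AKT and mTOR components, 13 rose, 9 fell and 5 did not pass (camera adjusted p = 0.54), and the list's median of 0.04 turns negative with library size alone, where 9 rose and 17 fell, and with the upper quartile, where 11 rose and 14 fell. Pik3ap1 and Pik3r6 rose by 2.27 and 2.23, while Inpp5d, the phosphatase SHIP1, fell by 2.88 and Pik3r2 fell by 1.83. Of 19 FOXO targets, 8 rose and 11 fell (camera adjusted p = 0.407), with S1pr1 and Tsc22d3 at -4.73 and -4.19 and Pik3ip1 at 3.29. These are transcript levels, and phosphorylation was not measured.

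Of 18 tested immune checkpoint genes, 11 rose and 7 fell (camera adjusted p = 0.67). Cd274, which encodes PD-L1 (chromosome 19, 29362107 to 29388095), rose from 670 ± 31.9 to 3347 ± 221 CPM (log2 fold change 2.32, SE 0.07, edgeR adjusted p = 6.04e-12). Pdcd1lg2, which encodes PD-L2, fell from 137 ± 13.1 to 6.11 ± 1.16 CPM, and Havcr2 fell by 3.53 on the log2 scale. Pilra, Siglec1 and Lgals9 rose by log2 fold changes of 5.78, 3.35 and 2.71.

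Interferon-stimulated genes rose in 32 of 32 tested members (camera adjusted p = 3.29e-47 with a preset correlation; adjusted p = 0.20 with an estimated correlation), and held 4.81% to 5.43% of the counts of each β-elemene library against 0.196% to 0.259% with PBS. Cmpk2 and Iigp1 rose by log2 fold changes of 9.32 and 8.27. Of 28 NF-kB targets, 27 rose and Ier3 fell (camera adjusted p = 1.38e-24 with a preset correlation; adjusted p = 0.20 with an estimated correlation), with Il1a at 8.54, Ccl3 at 8.27 and Cxcl1 at 7.26. Genes of MHC class I presentation rose in 18 of 20 cases, with 2 not passing (camera adjusted p = 1.89e-12 with a preset correlation; adjusted p = 0.24 with an estimated correlation). Nlrc5, the class I transactivator, Tap1 and Tap2 rose by 4.68, 3.91 and 3.17. Of 11 MHC class II genes, 1 rose, 4 fell and 6 did not pass (camera adjusted p = 0.744), and Ciita, the class II transactivator, fell from 77.7 ± 20.1 to 25.6 ± 1.55 CPM. In the inflammasome and cell death list 18 of 24 rose and 6 fell (camera adjusted p = 6.72e-07 with a preset correlation; adjusted p = 0.20 with an estimated correlation). Ptgs2, cyclooxygenase 2, Il18 and Nlrp3 rose by 9.04, 6.38 and 6.13, and Tfrc, the transferrin receptor, fell by 2.32. Ptgs2, Il18 and Il1b belong to the classical activation list as well. Tnf, Il1b, Ccl3 and Ccl4 belong to both the classical activation and the NF-kB list. The calls of these lists are therefore not separate results. Of 25 chemokine and receptor genes, 15 rose, 7 fell and 3 did not pass (camera adjusted p = 0.052), with Cxcl9 at 6.31 and the receptor Cxcr4 at -5.55.

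**Figure D3:**
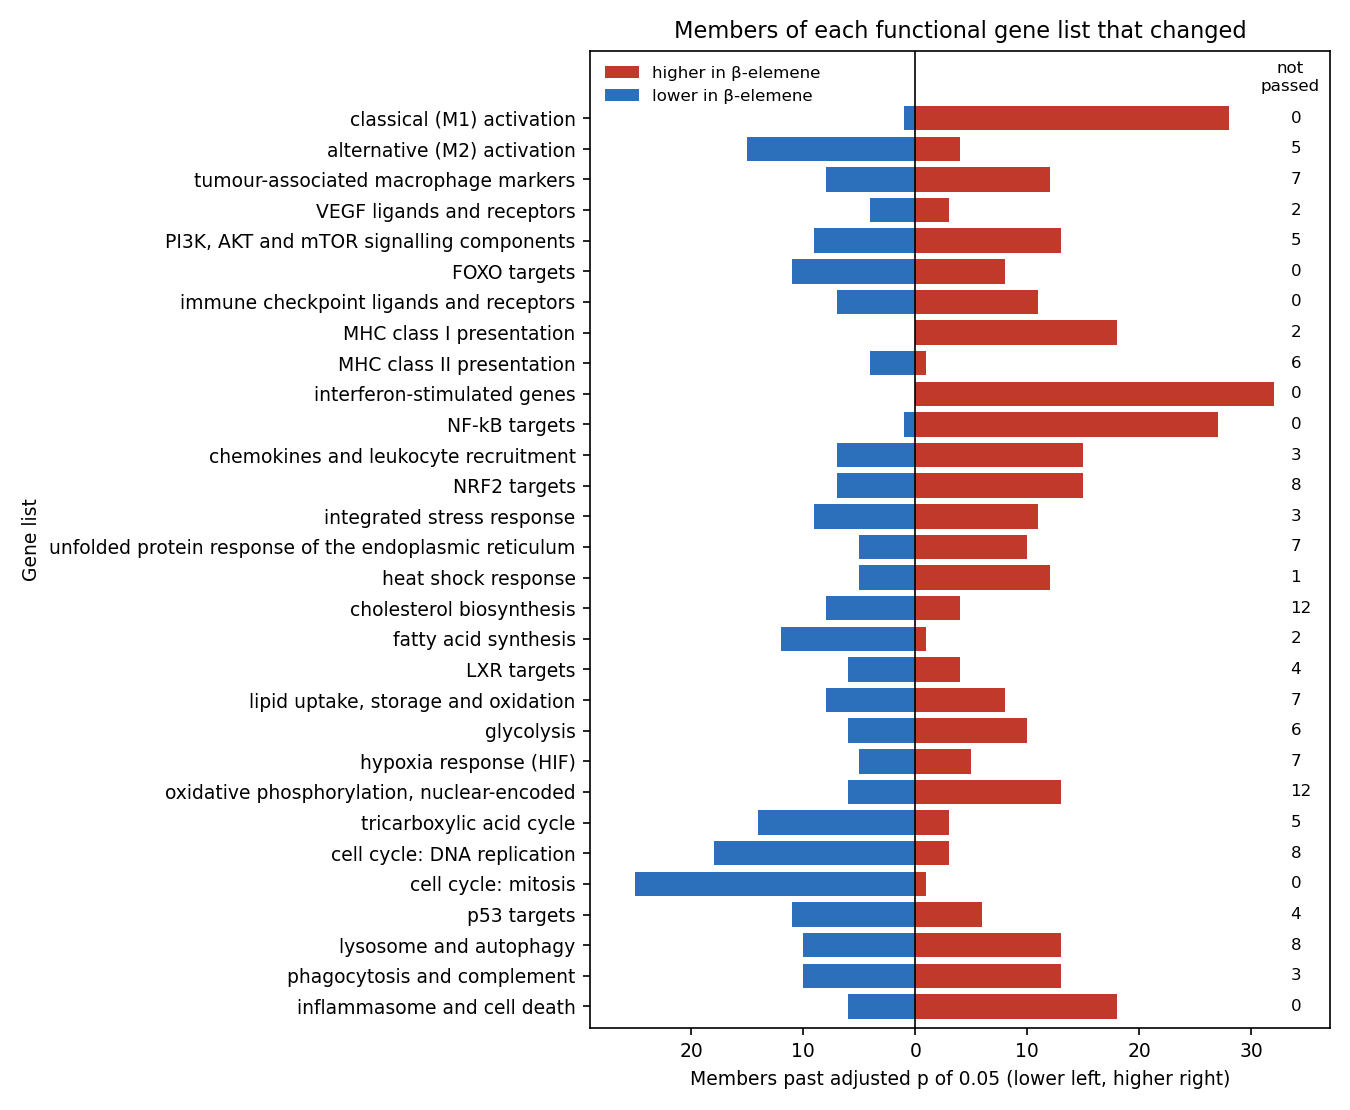
Number of tested members of each functional gene list that rose (red, to the right) or fell (blue, to the left) with β-elemene past an adjusted p of 0.05 over all genes tested, with the number that did not pass at the right edge. All 32 interferon-stimulated genes and 28 of 29 M1 genes rose, and 25 of 26 mitosis genes fell.

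Of 26 mitosis genes, 25 fell and Tpx2 rose (camera adjusted p = 9.30e-06 with a preset correlation; adjusted p = 0.79 with an estimated correlation). Bub1b, Cenpf and Cdc20 fell, with log2 fold changes of -4.26, -3.81 and -3.75. Of 29 DNA replication genes, 18 fell, 3 rose and 8 did not pass (camera adjusted p = 0.041 with a preset correlation; adjusted p = 0.79 with an estimated correlation). Mcm2 and Rrm2 fell, with log2 fold changes of -2.90 and -2.39, and Rfc3 rose by 1.80. This list's call was lost with library size alone (adjusted p = 0.123) and without β-elemene replicate 2 (adjusted p = 0.061). It was lost with a replicate block too (adjusted p = 0.057). Of 21 p53 targets, 6 rose, 11 fell and 4 did not pass (camera adjusted p = 0.67), with Mdm2 at 2.03 and Sesn1 at -3.82. The KEGG cell cycle pathway, chosen after its values were seen, had 39 of 116 genes rising and 60 falling (camera adjusted p = 0.271). The KEGG DNA replication pathway, chosen likewise, had 5 of 35 genes rising and 24 falling. Its camera adjusted p was 0.0395 with a preset correlation and 0.68 with an estimated correlation.

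Metabolic lists moved in both directions and none passed the list test. Of 15 fatty acid synthesis genes, 12 fell, 1 rose and 2 did not pass (camera adjusted p = 0.143), with Scd2, a fatty acid desaturase, falling from 226 ± 58.0 to 8.26 ± 4.04 CPM and Acsl4 rising by 1.34 on the log2 scale. Of 22 tricarboxylic acid cycle genes, 14 fell, 3 rose and 5 did not pass (camera adjusted p = 0.143), with Idh3a at -1.27. Of 22 glycolysis genes, 10 rose, 6 fell and 6 did not pass (camera adjusted p = 0.617), with Pfkfb3, an activator of glycolysis, rising from 40.7 ± 1.40 to 1133 ± 115 CPM and Pfkfb4 falling by 2.53 on the log2 scale. Of 31 nuclear genes of oxidative phosphorylation, 13 rose, 6 fell and 12 did not pass (camera adjusted p = 0.909), with Sdhb at -0.68, but 0 rose and 23 fell with the upper quartile, and 0 rose and 31 fell with library size alone. Cholesterol synthesis had 4 rising, 8 falling and 12 not passing (camera adjusted p = 0.67), with Dhcr7 at -4.03. The LXR targets had 4 rising, 6 falling and 4 not passing (camera adjusted p = 0.54), with Npc1 at -1.86 and Mertk at 1.71. Genes of lipid uptake, storage and oxidation had 8 rising, 8 falling and 7 not passing (camera adjusted p = 0.909), and Angptl4, with 0 counts over the β-elemene libraries against 139, was at least 28.8-fold lower after TMM scaling against a floor of 3 counts over the group (lower limit of the 95% counting interval 23.1). Hypoxia response genes had 5 rising, 5 falling and 7 not passing (camera adjusted p = 0.768), with Hif1a at 1.21 and Ndrg1 at -1.31.

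Stress and organelle lists were mixed as well. The NRF2 targets had 15 rising, 7 falling and 8 not passing (camera adjusted p = 0.744), with Gsr at 2.15 and Gclc at -1.62. The integrated stress response had 11 rising, 9 falling and 3 not passing (camera adjusted p = 0.962), with Wars at 2.23 and Slc7a5 at -2.50. The unfolded protein response had 10 rising, 5 falling and 7 not passing (camera adjusted p = 0.909), with Hspa5 at 1.37 and Pdia4 at -2.01. The heat shock response had 12 rising, 5 falling and 1 not passing (camera adjusted p = 0.609), with Hspa4l at 1.89 and Hsph1 at -1.64. Lysosome and autophagy genes had 13 rising, 10 falling and 8 not passing (camera adjusted p = 0.67), with Sqstm1 at 1.11 and Rragd at -3.30. Phagocytosis and complement genes had 13 rising, 10 falling and 3 not passing (camera adjusted p = 0.438), with Cfb at 5.47 and Itgav at -1.58. Tumour-associated macrophage markers had 12 rising, 8 falling and 7 not passing (camera adjusted p = 0.67), with Spp1 at -2.44 and Vcam1 at 4.45. The list medians of the LXR, MHC class II, NRF2, glycolysis, heat shock, hypoxia, integrated stress, lysosome, macrophage identity, osteoclast, endothelial, oxidative phosphorylation, phagocytosis, tumour-associated and unfolded protein lists change sign with library size alone. With that scaling 2 lysosome genes rose and 26 fell, 3 unfolded protein genes rose and 18 fell, 4 glycolysis genes rose and 15 fell, 7 NRF2 targets rose and 16 fell, and 5 integrated stress genes rose and 15 fell. Likewise 6 heat shock genes rose and 8 fell, 11 phagocytosis genes rose and 14 fell, 6 tumour-associated genes rose and 17 fell, 7 macrophage identity genes rose and 9 fell, 3 osteoclast genes rose and 5 fell, and 3 lipid uptake genes rose and 15 fell. It gave 2 rising and 12 falling for hypoxia, 2 and 10 for LXR targets, 1 and 8 for MHC class II, 2 and 14 for cholesterol synthesis and 0 and 21 for the tricarboxylic acid cycle. The upper quartile gave 3 rising and 10 falling for hypoxia, 2 and 8 for LXR targets, 1 and 6 for MHC class II and 3 and 12 for cholesterol synthesis. It gave 4 and 19 for lysosome, 3 and 11 for unfolded protein, 8 and 13 for tumour-associated and 12 and 11 for NRF2 genes. The medians named above as changing sign do so with the upper quartile too, apart from heat shock, macrophage identity, osteoclast and endothelial. The lipid uptake median is negative with TMM, the upper quartile and library size alone and positive with size factors by median of ratios. Median, mean and test do not share a sign for the VEGF, MHC class II, LXR, integrated stress, hypoxia, oxidative phosphorylation, lysosome, osteoclast and endothelial lists.

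Markers of macrophages were abundant in both groups. Macrophage identity genes had 11 rising, 5 falling and 1 not passing (camera adjusted p = 0.67), and Lyz2, the most abundant, stood at 9203 ± 398 against 6776 ± 378 CPM, a direction that flips with library size alone. Cebpa, a myeloid transcription factor, had a log2 fold change of -3.99 and Csf1r fell by 1.53, while Maf rose by 2.80. Monocyte markers had 7 rising, 3 falling and 2 not passing (camera adjusted p = 0.609), with Vcan at 8.07 and Ms4a4c at 6.44. Neutrophil markers had 5 rising, 2 falling and 3 not passing (camera adjusted p = 0.545), with Lcn2 at 6.46. Dendritic cell markers had 6 rising and 4 falling (camera adjusted p = 0.67), with Fscn1 at 4.08 and Batf3 at -4.54. Osteoclast markers had 5 rising, 4 falling and 1 not passing (camera adjusted p = 0.609), with Itgb3 at -3.89. Stromal markers had 6 falling, 1 rising and 4 not passing (camera adjusted p = 0.168), with Acta2 at -4.43 from 8.65 ± 0.450 CPM and Pdgfrb at 3.06. Endothelial markers had 2 rising, 2 falling and 1 not passing (camera adjusted p = 0.768), with Pecam1 at -2.99.

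Too few members of some lists were tested for a list test. Lymphocyte markers had 4 tested, of which 2 rose, 1 fell and 1 did not pass, with Lck at 35.5 ± 3.72 against 6.75 ± 0.976 CPM and Cd79b at a log2 fold change of -2.09. Cd3d, Cd3e and Cd3g had 0 to 2 counts over each group. Mast cell and basophil markers had 2 tested, of which Hdc rose, at 171 ± 19.4 against 10.6 ± 4.47 CPM, and Gata2 did not pass, while Fcer1a and Tpsb2 had 0 counts in both groups and Cpa3 had 8 with β-elemene and 0 with PBS. Erythroid and progenitor markers had 3 tested, of which 1 rose and 2 fell, with Pf4 at 26.5 ± 4.80 against 85.0 ± 12.4 CPM and Car2 rising by 1.36 on the log2 scale. Of the epithelial markers chosen for LLC cells, 2 were tested, Cdh1 and Muc1, and Muc1 stood at 0.417 ± 0.0661 against 1.36 ± 0.342 CPM. Cytosolic ribosomal protein genes had 6 rising, 8 falling and 16 not passing (camera adjusted p = 0.727), with Rpl4 at -0.23, and 25 of 30 fell with the upper quartile and 29 of 30 with library size alone. Immediate early genes had 12 rising and 3 falling (camera adjusted p = 0.168), with Klf6 at 2.89 and Jun at -2.01. The 13 mitochondrially encoded transcripts were not analysed here. Counts adjusted over the list alone equalled those over all genes, apart from 6 falling members in cholesterol synthesis, 5 in glycolysis and 4 among monocyte markers. None of the 8 list calls (5 up, 3 down, of 39 lists tested) held with an estimated correlation.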

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

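All alternatives here were fixed before the data were examined, and the tests on other splits of the libraries were specified after those results were seen. The number of genes changed was 8791 and lay between 8506 and 10169 over the alternatives with all 6 libraries, and between 8368 and 8773 when each library was left out. The number changed at least 2-fold was 4046, with 3753 to 5323 over the alternatives with all 6 libraries and 4048 to 4181 when each library was left out. Flt1 fell in each alternative, with a log2 fold change between -3.11 and -2.84 when each library was left out and -3.62 with library size alone. The number of gene lists shifted was 8, and it was 13 with no filter, where 43 lists could be tested. With fry, which does not compare a list with other genes, it was 29, and with an estimated correlation it was 0. It was 9 when each library was left out in turn. With an estimated correlation camera uses the 4 residual degrees of freedom, and with a preset correlation far more, set by the number of genes. A lost call can therefore come from the fewer degrees of freedom, from the correlation, or from both. How much each contributed was not tested. The inflammasome list lost its call at an estimated correlation of 0.028, and the alternative activation list at 0.065, against the preset 0.01. The other lists called had estimated correlations between 0.246 and 0.674. A large correlation between genes was therefore not needed for a call to be lost. The labels give no pairing by replicate number, and none was seen. Same-numbered libraries had correlations of -0.03, 0.05 and 0.01, and 1 of 3 correlated best with its own number. With so few libraries a pairing cannot be excluded. With a replicate block 8793 genes changed, 4040 at least 2-fold, and 8 lists shifted, of which 7 were among the 8 without the block. Vegfa passed under the upper quartile, library size alone, no filter, limma-voom and without β-elemene replicate 1, where it stood at -0.85. DESeq2 left the adjusted p of 2033 genes undefined. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each split other than the real one has libraries of both groups on each side, so the group difference adds to the spread within its sides. Few or no changed genes were therefore likely there from the start, and these splits are no measure of chance. The real split gave 8791 genes changed and the highest other 0 (1 of 10 as large), 4046 at least 2-fold and the highest other 0 (1 of 10 as large), and 8 lists shifted and the highest other 12 (9 of 10 as large). Depth limits what can be said of the size of the differences in summed counts of Retnla and Cd163, which had 2 counts each over the β-elemene libraries.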

Other observations

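All tests in this part were chosen after the results were seen. The genes and pathways named here for the first time were chosen after their values were seen as well.

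Among 291 KEGG pathways with at least 10 tested genes, taken from the annotation in the deposited table, 59 moved up and 2 down by camera with a preset correlation, and 0 with an estimated correlation. In the TNF signaling pathway 73 of 99 genes rose and 18 fell (camera adjusted p = 2.21e-11; adjusted p = 0.39 with an estimated correlation). The pathways that moved down were DNA replication, given above, and aminoacyl-tRNA biosynthesis. In aminoacyl-tRNA biosynthesis 34 of 44 genes fell and 4 rose (camera adjusted p = 0.0184 with a preset and 0.56 with an estimated correlation). Iars and Yars, which charge isoleucine and tyrosine transfer RNA, fell, with log2 fold changes of -1.54 and -1.48, while Wars rose by 2.23. The pathway's median of -0.65 was -0.61 with size factors by median of ratios, -0.97 with the upper quartile and -1.29 with library size alone. The KEGG VEGF and PI3K-Akt pathways had adjusted p of 0.143 and 0.265 by camera.

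Flt1 had 363 genes with a larger fall among the 11459 tested. Ifng, the interferon-gamma gene, had 43, 36 and 82 counts in the β-elemene libraries and 1, 0 and 0 in the PBS libraries.

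The rise of classical activation genes was set against 3 explanations. Scaling of the libraries to one another would need a median near or below 0 under some scaling, and the smallest median of the M1 list over 4 scalings was 5.57 (5.51 with genes near the floor at their bound), which argues against it. Interferon-gamma acting with its usual induction of MHC class II genes was taken to need a rise of that list of at least 2-fold. The list's median over PBS was 0.093 (95% bootstrap interval -0.54 to 0.21), so no such rise over PBS was seen. The bootstrap took the genes as independent, though their estimated correlation was 0.467. The PBS libraries may themselves be in a state that alters class II genes, so this ratio cannot decide the question. Interferon-gamma stays open, and its gene had counts almost only in the β-elemene libraries. A Toll-like receptor ligand, such as endotoxin carried with the drug, could give this profile, since at least 96.4% of tested NF-kB targets and of interferon-stimulated genes rose, but it cannot be told apart from the drug because no library had one without the other. An effect of β-elemene itself stays open as the explanation the design names.

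The fall of alternative activation genes was set against 2 explanations, of which scaling is argued against by the M2 list, whose median nearest 0 over 4 scalings was -1.82. The PBS libraries may instead hold macrophages in an interleukin-4-type state, since 13 of 18 markers of that state reached 10 CPM there, among them Egr2 at 323 CPM and Pdcd1lg2 at 137 CPM, while Retnla stood at 0.544 and Mgl2 at 0.764 CPM. Ccl17, Clec10a and Alox15 stood at 2.33, 0.570 and 0.401 CPM with PBS and did not differ between the groups past the threshold. The count looks at the PBS level only, and it includes Ccl22, which was higher with β-elemene (132 against 14.2 CPM). The markers and the level of 10 CPM were picked with these values known, so the count is no independent evidence. Whether tumour-cell medium or another exposure gave that state cannot be told apart here, because no library of macrophages without LLC cells was analysed. The letters M1 and M2 in the submitters' library names could mean that the libraries come from macrophages polarised to those states, in which case every β-elemene over PBS value here would compare polarisation states and not drug with vehicle, and this possibility was not tested and stays open.

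Cdh1 at 135 CPM in the PBS libraries raised the question of RNA from LLC or other epithelial cells, which the transwell membrane would hold back. Cells that express the 13 other epithelial markers would bring those transcripts too. The highest of these was Muc1 at 1.36 CPM, with Krt18 and Epcam both at 0.0258 CPM, which argues against such cells as the source. No library of LLC cells was analysed, so it is not known here whether LLC cells express these markers. RNA from LLC cells therefore stays open. Cdh1 is among the markers of an interleukin-4-type state counted above, and that count took its expression by the macrophages themselves as given. This expression is a hypothesis that was not tested further.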
